A study of Mus musculus with 6 samples.

How the data were processed

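Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in pancreatic islets of 16-week-old mice. The labels describe 6 libraries in 3 groups of 2. Islets of control mice received a GFP adenovirus (control-GFP), islets of mice lacking Rictor in beta cells received the same GFP virus (knockout-GFP), and islets of knockout mice received an adenovirus carrying Acsl4 (knockout-Acsl4). Per the labels' protocols, virus was applied for 48 h ex vivo, about 50 islets were lysed per sample, libraries were amplified with 12 PCR cycles, and paired reads of 50 bp were sequenced on an Illumina HiSeq instrument. The labels do not say whether the libraries of a group came from separate mice. The p-values of comparisons between groups therefore measure only the spread between these samples, which may be technical.

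The authors deposited a peak list per library, with the chromosome, start, end, name and a value for each peak, and no header. FastQC, Trimmomatic, BWA 0.7.10, SAMtools and MACS2 2.1.1 are named per the submitters' processing notes, without roles or settings. The deposited value was read as the −log10 q-value of the authors' peak caller, because the smallest value in every list lies just above 1.30, the −log10 of 0.05. No column name states this, so the reading is inferred from the values. Each list belongs to a single library, so peaks were taken as called per library. The read depth of each library is not given in the sources used here, and the number of called peaks stands in its place. These values are each peak's own score and were used only to rank or describe peaks within a list.

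The submitters' processing notes name the human builds hg38 and GRCh38, although the organism is mouse. The chromosomes are 1 to 19, X and Y, and peaks lay at the ends of mouse GRCm38 genes far more often than after a shift, so coordinates were treated as GRCm38 and are given 1-based. Genes were taken from a RefSeq gene table of that assembly, restricted to 21883 protein-coding genes. This table holds gene starts and ends without strand or exons. The planned promoter window was therefore replaced by 1000 bp on either side of both ends of a gene, called a gene end here, and the planned classes exon and intron by gene body. All 226 unique genes of the 13 fixed lists matched the table. A search for 9 motifs was planned and not run, since no genome sequence was used here.

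Peaks were counted as shared when they overlapped by at least 1 bp. Peaks of all 6 libraries were merged into 13633 regions. For each of the 3 comparisons, regions with a peak in both libraries of a group and in neither of the other group were counted, and the same count was made for the other 2 ways of splitting the 4 libraries. Gene counts used the same pattern with a peak at a gene end, so a gene can have different peaks in its libraries. No test per region was made, because 2 libraries against 2 cannot give a two-sided exact permutation p below 0.333. Pairwise overlap was tested over all 15 ways of pairing the 6 libraries, with a smallest possible p of 0.0667. Members of fixed gene lists with a peak at a gene end were compared with all other protein-coding genes in each library by two-sided Fisher exact tests, adjusted by Benjamini-Hochberg over 78 tests. Such tests run across genes and describe a library, not a group. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. The gene-end share expected by position was taken from peaks shifted by 100000 bp in both directions.

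Genes are named by a rule set before the data were examined. It takes Rictor, Acsl4 and Foxo1, the 10 genes per comparison and direction with a peak at a gene end in both libraries of a group and neither of the other that have the highest mean score percentile, members of the fixed lists with that pattern, the 10 genes with such a peak in the most libraries, and up to 4 examples per list. A score percentile ranks a peak within its own library and was averaged over the libraries named. The fixed lists cover beta cell identity, dedifferentiation and disallowed genes, other endocrine cells, acinar and ductal cells, endothelial, stromal and immune cells, antioxidant defence, fatty acid metabolism, the mTORC2, AKT and FOXO pathway, FOXO targets, ER stress, immediate early genes, housekeeping genes and genes silent in islets. The single marked member of the acinar and ductal list is not reported here by name.

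Alternatives were an overlap of at least 50% of the shorter peak, the better 50% of each list by score, equal list lengths of 525 peaks, autosomes only, a gene-end window of 3000 bp, covered length in place of peak number, pairing by replicate number, and leaving out each library in turn. Alternatives chosen after the data were seen were regions at gene ends only, leaving out a pair of libraries, crossed pairs, splits at other list lengths, and gene families by symbol. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and bedtools 2.31.1 to check overlaps. The procedure was tested on simulated data for knockout-GFP against control-GFP over 21883 genes. All of 200 planted knockout-only regions were recovered (100%). They had been placed in both knockout lists and in no control list, so this checks the counting code and not its sensitivity or false calls. Of 200 random gene lists, 5% had a raw p under 0.05.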

Results

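Open chromatin was profiled by ATAC-seq in mouse pancreatic islets after loss of Rictor, the defining subunit of the kinase complex mTORC2, in beta cells, and after added expression of Acsl4, an acyl-CoA synthetase that activates long-chain polyunsaturated fatty acids. The study's title asks whether more Acsl4 without mTORC2 drives beta cell dedifferentiation through FoxO1 and reactive oxygen species. There were 6 libraries, 2 in each of 3 groups, named here by their labels as control-GFP, knockout-GFP and knockout-Acsl4. The lists held 4442 and 1628 peaks in the libraries labelled control-GFP 1 and 2, 2206 and 4257 in those labelled knockout-GFP 1 and 2, and 525 and 5874 in those labelled knockout-Acsl4 1 and 2. Covered length ran from 91.3 kb in the library labelled knockout-Acsl4 1 to 1658 kb in that labelled knockout-Acsl4 2. Group means were 3035 ± 1990 peaks for control-GFP, 3232 ± 1450 for knockout-GFP and 3200 ± 3782 for knockout-Acsl4 (SD, n = 2 each), and every exact permutation p between groups was 1.

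The targeted genes were examined first. Rictor (chromosome 15, 6708349 to 6800401) carried no peak in any of the 6 libraries, controls included, so the peak lists do not check the knockout. Acsl4 (chromosome X, 142317993 to 142390802) carried 6 peaks inside the gene in the libraries labelled control-GFP 1 and knockout-GFP 1, and none in the library labelled control-GFP 2, in that labelled knockout-GFP 2, or in either library labelled knockout-Acsl4. A peak over Acsl4 coding sequence had been foreseen before the data were examined for the Acsl4 virus only. The 6 peaks lay between 142320680 and 142351606 and were 144 to 647 bp wide. The widest spanned 142350960 to 142351606 in both libraries, with a score of 50.3 in the library labelled control-GFP 1 and 91.2 in that labelled knockout-GFP 1. Their score percentiles ran from 69.1 to 98.5 in the former and from 93.9 to 98.2 in the latter. The library labelled control-GFP 1 also had a peak at an Acsl4 gene end, from 142390416 to 142390727. Foxo1, the forkhead transcription factor named in the title (chromosome 3, 52268337 to 52350109), had a single peak at its gene end, in the library labelled control-GFP 2 only, at 52268439 to 52268576 with a score of 2.40. Whether the Acsl4 peaks lie on exons was not analysed here. All directions below hold for the labels as deposited.

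**Figure D1:**
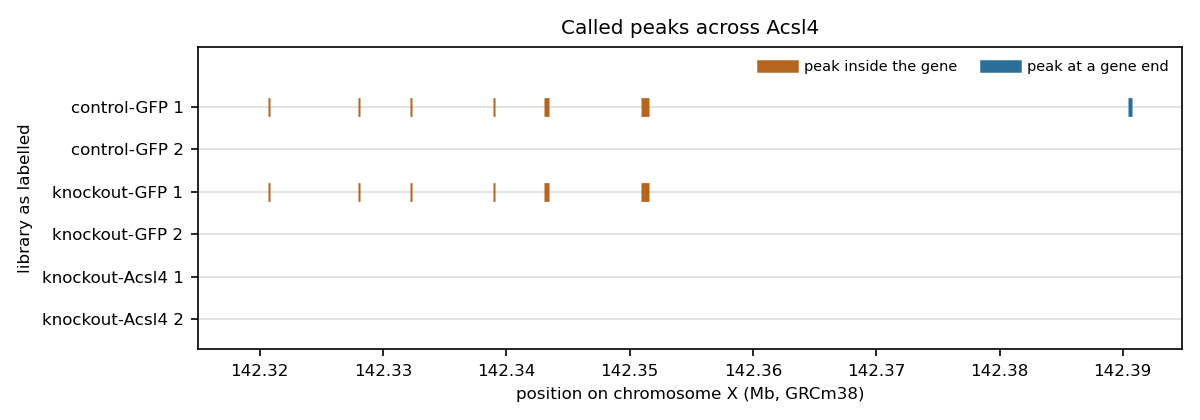
Called peaks across Acsl4 on chromosome X (GRCm38, position in Mb) in each of the 6 libraries as labelled, with peaks inside the gene in brown and peaks at a gene end in blue. The 6 inside peaks stand at nearly the same positions in the libraries labelled control-GFP 1 and knockout-GFP 1 and are missing from the other lists.

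The share of peaks at the ends of protein-coding genes was highest in 3 libraries. The gene-end share was 69.9% (95% exact interval 68.5 to 71.2) in the library labelled control-GFP 1, 66.7% (64.7 to 68.7) in that labelled knockout-GFP 1 and 75.0% (73.7 to 76.3) in that labelled knockout-GFP 2. It was 35.8% (31.7 to 40.1) in the library labelled knockout-Acsl4 1, 21.6% (19.6 to 23.6) in that labelled control-GFP 2 and 4.82% (4.28 to 5.40) in that labelled knockout-Acsl4 2. Peaks shifted along the chromosome fell at gene ends in 3.21% to 6.60% of cases. The observed share was 12.0, 11.1 and 11.4 times the shifted share in the libraries labelled control-GFP 1, knockout-GFP 1 and knockout-GFP 2. It was nearly as high, 10.4 times, in that labelled knockout-Acsl4 1. The ratio was 6.21 in that labelled control-GFP 2 and 1.50 in that labelled knockout-Acsl4 2. In the list labelled knockout-Acsl4 2, 56.3% of peaks were intergenic and 59.1% had a score under 2, and 97.1% of its regions were found in no other library. Group means of the gene-end share were 45.7% ± 34.2 for control-GFP, 70.9% ± 5.87 for knockout-GFP and 20.3% ± 21.9 for knockout-Acsl4 (SD, n = 2 each). The exact permutation p was 0.667 for knockout-GFP against control-GFP and 0.333, the smallest possible, for knockout-Acsl4 against knockout-GFP.

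**Figure D2:**
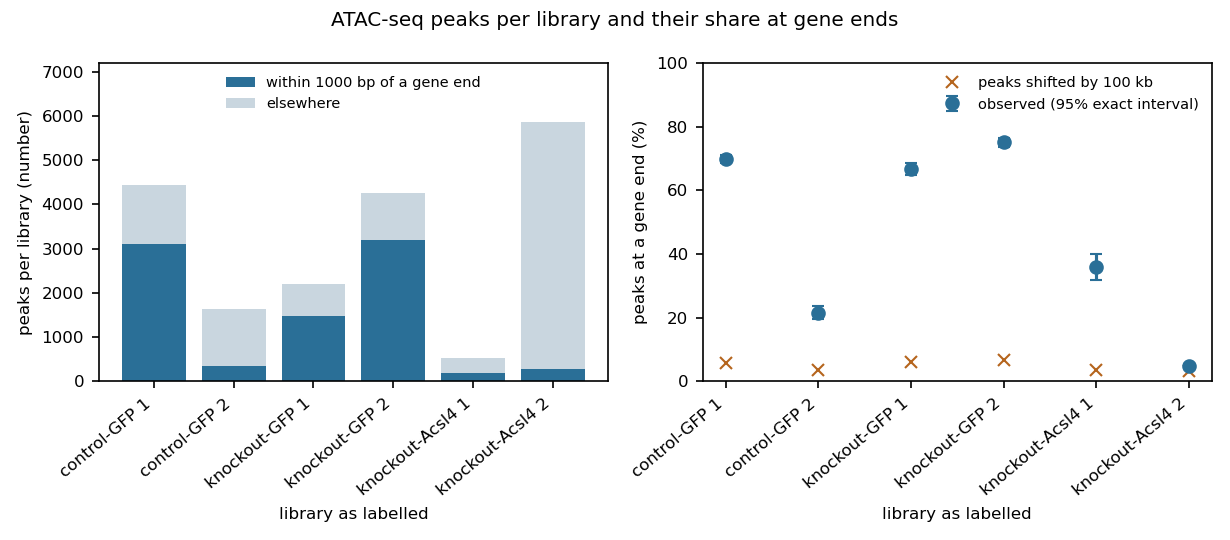
Left, the number of ATAC-seq peaks in each library as labelled, divided into peaks within 1000 bp of a gene end and peaks elsewhere. Right, the gene-end share in percent with its 95% exact interval, beside the share of the same peaks shifted by 100 kb, which lies between 3.21% and 6.60%.

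Few genes were marked in most libraries. Ripk2, an innate immune signalling kinase, and the neighbours Ccnk, a cyclin of the transcription elongation kinases, and Setd3, a histidine methyltransferase of actin, had a gene-end peak in all 6. The Ripk2 peak spanned 16163379 to 16164266 on chromosome 4 in the library labelled control-GFP 1, and that of Ccnk and Setd3 108179300 to 108179780 on chromosome 12. Lars2, the mitochondrial leucyl-tRNA synthetase, had such a peak in 5 libraries with a mean score percentile of 94.0, and Rab8a, a GTPase of vesicle transport, in 5 with 91.3. Pwwp2a (87.7), Chchd7 and Plag1 (86.7), Garem1 (85.6) and the oligosaccharyltransferase subunit Stt3a (85.4) also had one in 5. Of the 13633 merged regions, 10489 (76.9%) were found in 1 library and 50 in all 6. Only 2 of those 50 lay at a gene end (4%), whereas 78.5%, 81.2% and 76.8% of the regions found in 2, 3 and 4 libraries did. The highest score of every list belonged to the same region, chromosome 2 from 98666248 to 98667327, and 13 of the 50 lay at the start of chromosome 9, between 3000006 and 3038222. A high score in all lists does not by itself show open chromatin, and whether these regions are open was not tested.

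Libraries of a group were not shown to share more peaks than libraries of different groups. The libraries labelled knockout-GFP 1 and 2 shared 67.8% of the shorter list (95% exact interval 65.8 to 69.7). The library labelled control-GFP 1 shared 64.1% (62.0 to 66.1) with that labelled knockout-GFP 1 and 61.4% (59.9 to 62.9) with that labelled knockout-GFP 2, but 24.6% (22.6 to 26.8) with the other control library. The libraries labelled knockout-Acsl4 1 and 2 shared 12.6% (9.86 to 15.7), while the former shared 61.5% with that labelled control-GFP 1 and 63.8% with that labelled knockout-GFP 2. The 12.6% stands for 66 of 525 peaks. Regions called in all 6 libraries numbered 50, were not removed, and can make up most of that overlap. The mean over same-group pairs was 35.0%, against 32.2% over the other pairs, and 4 of the 15 pairings gave a mean as high (exact permutation p = 0.267). Of the strongest 25% of gene-end peaks in the library labelled knockout-GFP 2, 87.0% (84.5 to 89.2) were found in that labelled control-GFP 1, against 39.9% (36.5 to 43.4) of the weakest 25%. Such peaks of the library labelled knockout-Acsl4 2 were found in that labelled knockout-GFP 2 at 21.1% in both the strongest and the weakest 25%. In the library labelled control-GFP 1 they were found at 22.5% and 11.3%, and in that labelled knockout-GFP 1 at 14.1% and 4.23%.

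**Figure D3:**
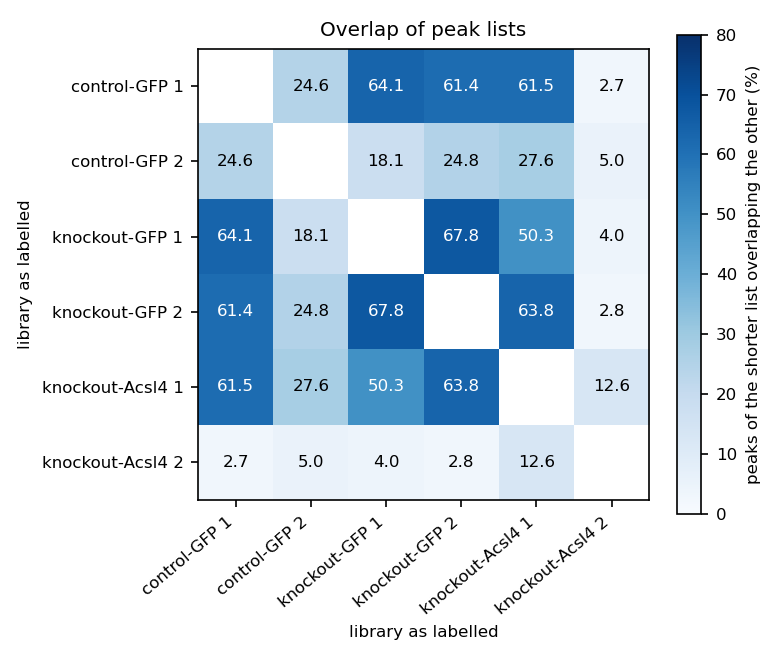
Share of the shorter peak list that overlaps the other list, in percent, for each of the 15 pairs of libraries as labelled. The libraries labelled knockout-GFP 1 and 2 share 67.8%, and all pairs with that labelled knockout-Acsl4 2 share 12.6% or less.

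The comparison of knockout-GFP with control-GFP asks what loss of Rictor does to open chromatin. Most regions open in both libraries labelled knockout-GFP were also called in the library labelled control-GFP 1, which held 1247 of 1491 (83.6%, 95% exact interval 81.7 to 85.5), whereas that labelled control-GFP 2 held 286 (19.2%). As labelled, 234 regions had a peak in both knockout libraries and neither control, and 25 the reverse (58 and 17 at equal list lengths). At gene ends these counts were 186 and 13 regions, or 227 and 20 genes. The gene with the highest scores among the 227 was the predicted gene Gm32584 (chromosome 5, 36661020 to 36661357 in the library labelled knockout-GFP 1), with a mean percentile of 96.4. A peak at 76351139 to 76351276 on chromosome 15 served both Maf1, a repressor of RNA polymerase III, and Sharpin, a part of the linear ubiquitin ligase (88.6). Phf12 (86.7), the phospholipid synthesis enzyme Selenoi (83.5), the histone chaperone subunit Ubn2 (82.1), the ubiquitin ligase receptor Zyg11b (80.9), the casein kinase subunit Csnk2b with its neighbour Gpank1 (80.4) and the cytosolic chaperone Hsp90aa1 (80.4) followed.

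Among the fixed lists, 3 members had this knockout-only pattern and 0 the reverse. They were Ppia (62.8) and Rplp0 (28.5) of the housekeeping list and Acsl3, a relative of Acsl4 (15.8). No member of the beta cell identity, dedifferentiation, antioxidant, FOXO target or mTORC2 lists had either pattern. Of all 21883 protein-coding genes, 227 and 20 had them, so lists of 20 or 25 genes were likely to hold none. This absence therefore says nothing about these lists. The control-only genes were led by the focal adhesion protein Zyx (77.4), with its peak at 42349349 to 42350056 on chromosome 6 in the library labelled control-GFP 1, the Golgi protein Gopc (71.6), the ribosomal oxygenase Riox2 (66.7) and the TFIID subunit Taf8 (64.3). The neighbours Cct7, a chaperonin subunit, and Pradc1 (63.2), Dap3 of the mitochondrial ribosome (61.8), Fam135a (60.9), the protease Tasp1 (59.8) and the ubiquitin ligase Ube3c (59.5) completed the 10. The other 2 splits of these 4 libraries gave 160 against 21 and 1242 against 8 regions, with the pair that held the library labelled control-GFP 2 lower each time. The knockout-only and control-only counts became 1205 and 1205 without the library labelled control-GFP 1, 244 and 1673 without that labelled control-GFP 2, 1605 and 31 without that labelled knockout-GFP 1, and 762 and 119 without that labelled knockout-GFP 2.

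Knockout-Acsl4 against knockout-GFP asks what added Acsl4 does in islets lacking Rictor. As labelled, 1231 regions were called in both knockout-GFP libraries and in neither knockout-Acsl4 library, and 2 the reverse. At equal list lengths these counts were 102 and 1, and the other 2 splits of the 4 lists as deposited gave 11 against 40 and 13 against 77 regions. None of those 2 lay at a gene end. They were 21613996 to 21614173 on chromosome 3 and 74184201 to 74184473 on chromosome 9, named after their values were seen. Of the 1231, 1011 lay at gene ends. The libraries labelled knockout-Acsl4 1 and 2 shared 66 peaks, and 56 regions were in all 4 lists, which left little room for knockout-Acsl4-only regions. These libraries marked 224 and 344 genes at gene ends, against 1792 and 3786 in those labelled knockout-GFP 1 and 2. The counts therefore do not show a loss of open chromatin with Acsl4. At the gene level 1266 genes were marked in knockout-GFP only and 2 in knockout-Acsl4 only, the ubiquitin ligase Marchf8 (mean percentile 72.2) and the predicted gene Gm46382 (45.0). These genes lie on chromosomes 6 and 12, so neither was marked by a region called only in both knockout-Acsl4 libraries. The highest scores in knockout-GFP belonged to Gm32584 (96.4), the tetrahydrobiopterin recycling enzyme Qdpr (95.7; chromosome 5, 45450215 to 45450605), the zinc finger genes Zfp78 (95.6) and Zbtb5 (94.9), Ifrd1 (94.8), the aminopeptidase Dnpep (94.6), the neighbours Gmfg and Samd4b (94.5), and the neighbours Mylpf and Tbc1d10b (94.1).

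Fixed-list memberships marked in both libraries labelled knockout-GFP and neither labelled knockout-Acsl4 numbered 20, against 0 in the other direction. ER stress genes were the most frequent, with Eif2ak3, the stress kinase PERK (91.2), the ER chaperones Hsp90b1 (87.3) and Hspa5, also called BiP (51.4), the stress transcription factor Ddit3, also called CHOP (83.0), Dnajb9 (52.8) and Pdia4 (48.5). Both libraries labelled knockout-GFP marked 8 ER stress members, and 6 of these had the pattern. Over all genes, 1266 of the 1445 marked in both had it, so ER stress genes did not have the pattern more often than genes in general. FOXO targets with the pattern were Sesn3 (73.8), the mitochondrial superoxide dismutase Sod2 (60.4), which is also on the antioxidant list, and Irs2 (17.4), which is also on the mTORC2 list. Others were Gsk3b (55.9) and Pik3ca (29.3) of the mTORC2 list, Lpcat3 (75.2), Acadm (56.1) and Acsl3 (15.8) of fatty acid metabolism, the immediate early gene Klf6 (83.1), and the housekeeping genes Ppia, Polr2a (33.6) and Rplp0. The library labelled knockout-Acsl4 1 held 525 peaks, and that labelled knockout-Acsl4 2 had 4.82% of its peaks at gene ends. Of the 186 gene-end regions in the library labelled knockout-Acsl4 1, 158 (84.9%, 95% exact interval 79.0 to 89.8) were also called in that labelled knockout-GFP 2. The knockout-GFP-only count was 3839 without the library labelled knockout-GFP 1 and 1908 without that labelled knockout-GFP 2, and the knockout-Acsl4-only count 5735 without that labelled knockout-Acsl4 1, 174 without that labelled knockout-Acsl4 2 and 5 without that labelled knockout-GFP 2.

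Knockout-Acsl4 against control-GFP gives the combined difference. As labelled, 261 regions were called in both control-GFP libraries and neither knockout-Acsl4 library, 209 of them at gene ends, and 3 the reverse. At equal list lengths these counts were 55 and 1, and the other 2 splits of the lists as deposited gave 166 against 19 and 55 against 4 regions. The 3 were the 2 named for the previous comparison and 60925817 to 60926049 on chromosome X, and none lay at a gene end. As the knockout-Acsl4 lists shared 66 peaks and 51 regions were in all 4 lists, few regions could be knockout-Acsl4-only. At the gene level the counts were 289 control-only genes and 1 knockout-Acsl4-only gene, Gm46382 (mean percentile 45.0), which lies on chromosome 12 and at none of the 3 regions. The control-only genes were led by the neighbours Nectin2, an adhesion receptor, and Tomm40, the mitochondrial import channel (95.6; chromosome 7, 19715477 to 19715980 in the library labelled control-GFP 1), followed by Ifrd1 (95.1), Abtb1 and Podxl2 (94.9), the ubiquitin ligase Cblb (94.8), Svip (93.7), Arl4a (93.5), the phosphatase subunit Ppp2r1a (93.4) and Opn3 (93.3). List members with this pattern were Eif2ak3 (88.6), Gsk3b (87.6), Hspa5 (82.9), Klf6 (61.5) and Polr2a (30.5), and these 5 were also marked in both knockout-GFP libraries. Without the library labelled control-GFP 1 or 2 the control-only count was 1455 or 4055. The knockout-Acsl4-only count was 5729 or 194 without the library labelled knockout-Acsl4 1 or 2, and 9 or 5 without that labelled control-GFP 1 or 2.

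Genes of the ER stress response stood out among the fixed lists. In the library labelled control-GFP 1, 13 of 15 members (86.7%) had a gene-end peak, against 16.6% of other genes (odds ratio 32.6, Fisher exact adjusted p = 3.53e-07). In the library labelled knockout-GFP 2 the count was also 13 (odds ratio 31.2, Fisher exact adjusted p = 3.53e-07), and in that labelled knockout-GFP 1 it was 8 (odds ratio 12.9, Fisher exact adjusted p = 0.000197). The counts were 2, 1 and 1 in the libraries labelled control-GFP 2, knockout-Acsl4 1 and knockout-Acsl4 2, and did not pass. Atf3, the calcium-binding chaperone Calr, Eif2ak3 and Hspa5 were each marked in 4 libraries. Housekeeping genes passed in the libraries labelled control-GFP 1 (9 of 20, odds ratio 4.09, Fisher exact adjusted p = 0.0444) and knockout-GFP 2 (9 of 20, odds ratio 3.92, adjusted p = 0.0479), with Polr2a marked in 4 libraries and Pgk1, Ppia and Psmb2 in 2. FOXO targets passed in the library labelled control-GFP 1 (9 of 20, odds ratio 4.09, Fisher exact adjusted p = 0.0444) and not in that labelled knockout-GFP 2 (8 of 20, adjusted p = 0.0993), a difference that was not tested. Irs2, Sesn3 and Sod2 were marked in the same 3 libraries, those labelled control-GFP 1, knockout-GFP 1 and knockout-GFP 2, and the cell cycle gene Ccng2 in 2. The FOXO target call ended with a 3000 bp window (odds ratio 3.54, Fisher exact adjusted p = 0.0718), with the better 50% of each list (4.14, 0.127) and at equal list lengths (5.76, 0.711). Both housekeeping calls ended with the better 50% (odds ratios 1.70 and 2.47) and at equal lengths (0 in each), and that in the library labelled knockout-GFP 2 also without that labelled control-GFP 1 (odds ratio still 3.92, Fisher exact adjusted p = 0.0798). At equal lengths ER stress passed only in the library labelled knockout-GFP 2 (odds ratios 7.97 and 7.99, Fisher exact adjusted p = 0.502, in the other 2). The 6 results of the main setting, all higher, were those that passed among 78 tests, of which 15 had a raw p under 0.05.

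Beta cell identity genes passed in none of the 6 libraries. Their share was 12% against 16.7% of other genes in the library labelled control-GFP 1 (Fisher exact adjusted p = 1) and 8% against 17.3% in that labelled knockout-GFP 2 (Fisher exact adjusted p = 0.638). Of 25 such genes, Mafa and Nkx6-1 had a gene-end peak in the libraries labelled control-GFP 1 and knockout-GFP 2, and Pcsk2 in that labelled control-GFP 1, while 22 of the 25, including Ins1, Ins2 and Pdx1, had none in any library. Of 20 dedifferentiation and disallowed genes, Myc was marked in the library labelled control-GFP 1, and Acot7 and Slc16a1 in that labelled knockout-GFP 2. Lists for other endocrine cells, for endothelial, stromal and immune cells and for genes silent in islets had 0 members marked in any library, and the acinar and ductal list had 1 of 15, in the library labelled knockout-GFP 2. Antioxidant genes were marked for 4, 0, 2, 8, 0 and 1 of 20 members in the libraries labelled control-GFP 1 and 2, knockout-GFP 1 and 2, and knockout-Acsl4 1 and 2. They included Sod2 in 3 libraries and Keap1, Nfe2l2 and Sod1 in 2 each. In the same order, fatty acid metabolism had 7, 1, 4, 4, 0 and 1 of 20, with Acsl1 in 4 libraries, Acadm and Lpcat3 in 3 and Acsl3 in 2. The mTORC2, AKT and FOXO list had 8, 2, 3, 6, 0 and 0 of 20, with Gsk3b in 4 libraries, Irs2 and Pik3ca in 3 and Mtor in 2. Immediate early genes had 7, 2, 3, 7, 0 and 2 of 15, with Atf3 and Klf6 in 4 libraries and Egr1 and Fos in 2. None of these lists passed after adjustment in any library.

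**Figure D4:**
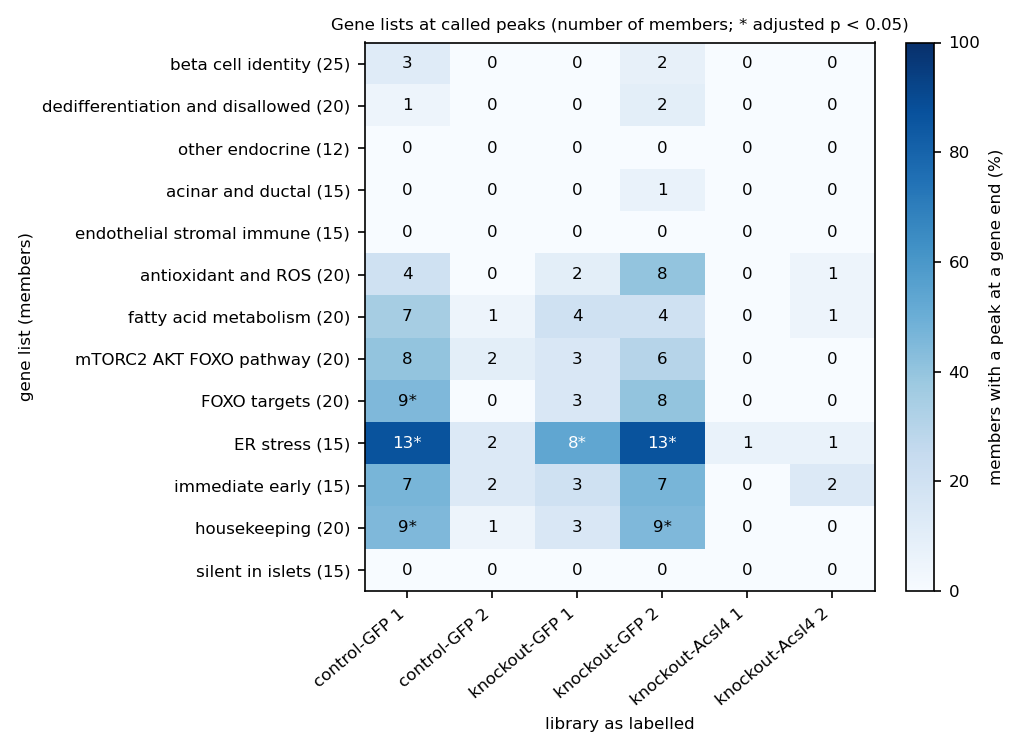
Members of each fixed gene list with a peak at a gene end, in percent by colour and as a number in each cell, for each library as labelled. Stars mark list and library pairs past the adjusted threshold, with ER stress highest at 13 of 15 members in the libraries labelled control-GFP 1 and knockout-GFP 2.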

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

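Restriction to gene ends, leaving out a pair of libraries, crossed pairs and splits at other list lengths were chosen after the data were seen; the other alternatives were planned. Same-group overlap stayed above the other pairs in 4 of 4 alternatives, at 26.8% to 42.6% (exact permutation p 0.267 to 0.4), never past the threshold. The knockout-GFP-only count against control-GFP (234) was 142 with the better 50% of each list, 58 at equal lengths, 244 to 1605 leaving out each library and 3818 without the libraries labelled control-GFP 1 and knockout-GFP 1. The control-only count (25) was 24 and 17 with those lists, 13 at gene ends, 31 to 1673 leaving out each library and 1219 without that pair. For knockout-Acsl4 against knockout-GFP, 2 became 1 at equal lengths, 0 at gene ends, 3 to 5735 leaving out each library and 186 without the libraries labelled knockout-GFP 1 and knockout-Acsl4 2; 1231 became 610 with the better 50%, 102 at equal lengths, 1254 to 3839 and 3902. For knockout-Acsl4 against control-GFP, 3 became 1 at equal lengths, 0 at gene ends, 5 to 5729 and 200 without the libraries labelled control-GFP 2 and knockout-Acsl4 2; 261 became 165 with the better 50%, 55 at equal lengths, 270 to 4055 and 4119. Leaving out a library loosens the criterion by construction, and shorter lists hold fewer regions. The gene-end share of knockout-GFP was 76.8% at 3000 bp, a wider window, and the shares under other windows and list lengths moved by less than the SD. Leaving out a library leaves the share of the other, 21.6% or 69.9% for control-GFP, 66.7% or 75.0% for knockout-GFP and 4.82% or 35.8% for knockout-Acsl4. The 6 list results became 3 with the better 50%, 1 at equal lengths and 2 to 6 leaving out each library (2 without that labelled control-GFP 1). Leaving out another library changes only the adjustment of these 6. Of 18 alternatives that change the list or window, 9 passed, 7 did not, and housekeeping genes at equal lengths fell to an odds ratio of 0 in the libraries labelled control-GFP 1 and knockout-GFP 2 (Fisher exact adjusted p = 1 in each), which shortening to 525 peaks brings about and which shows no lower share. Pairing by replicate number as a block gave the same counts (234 and 25, 1231 and 2, 261 and 3) by construction. The correlation of same-numbered libraries was −0.171 for knockout-GFP against control-GFP, −0.233 for knockout-Acsl4 against knockout-GFP and 0.280 for knockout-Acsl4 against control-GFP. These weak values come from 2 pairs of libraries per comparison and do not show that libraries of the same number belong together. Crossed pairs again gave 234 and 25, and 1231 and 2. The planned motif windows, backgrounds and list lengths were not run. Read depth is unknown, so a missing peak shows no closed chromatin.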

Other observations

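Chosen only after the result was seen were the tests of gene families, of ER stress against housekeeping genes, of overexpression as labelled, of the endogenous gene, of another build, of an Acsl4 effect on the gene-end share, of the short list and of loss of Rictor, the splits at other list lengths, the comparisons matched by score, chromosome or gene end, and the bootstrap interval. Gene families were defined by the start of the symbol. Of 114 two-sided Fisher exact tests over 19 families, 26 passed with a higher and 18 with a lower share of genes marked at a gene end than other genes. Translation initiation factors were marked for 28 of 56 members (50%) in the library labelled knockout-GFP 2 (odds ratio 4.81, exact adjusted p = 2.54e-07), 17 in that labelled control-GFP 1 (adjusted p = 0.0305) and 12 in that labelled knockout-GFP 1 (adjusted p = 0.00586). Heat shock proteins reached 14, 4, 12 and 16 of 30 in the libraries labelled control-GFP 1 and 2 and knockout-GFP 1 and 2, all 4 past the threshold. Rab GTPases, which direct vesicle traffic, passed in 5 libraries, including that labelled knockout-Acsl4 1 (5 of 69, odds ratio 7.70, exact adjusted p = 0.00323). Proteins of ER translocation and coat vesicles had 21, 12 and 20 of 52 members marked in the libraries labelled control-GFP 1, knockout-GFP 1 and knockout-GFP 2.

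Zinc finger genes named Zfp were marked for 91 of 397 members (22.9%) in the library labelled control-GFP 1 (odds ratio 1.50, exact adjusted p = 0.00513) and 66 in that labelled knockout-GFP 2, which did not pass, and the difference was not tested. Of 1110 olfactory receptors, 0, 1, 0, 0, 1 and 3 were marked across the 6 libraries, below other genes in each. Potassium channels had 2, 0 and 1 of 94 marked in the libraries labelled control-GFP 1, knockout-GFP 1 and knockout-GFP 2, also below other genes. Keratins were likewise lower in these libraries, with 0, 0 and 1 of 112. ER stress genes exceeded housekeeping genes in the libraries labelled control-GFP 1 and knockout-GFP 2 (13 of 15 against 9 of 20 in each, Fisher exact adjusted p = 0.0473), while in that labelled knockout-GFP 1 it was 8 against 3 (adjusted p = 0.0541). Of 966 genes on chromosome X, 81 (8.39%) and 0 were marked in the libraries labelled control-GFP 1 and 2. In those labelled knockout-GFP 1 and 2 it was 9 (0.932%) and 37 (3.83%), and in those labelled knockout-Acsl4 1 and 2 it was 1 and 4. In the same order, autosomal genes were marked at 17.3%, 2.12%, 8.63%, 18.1%, 1.08% and 1.65%, so the chromosome X share was lower in each library. The sex of the mice is not given in the sources used here.

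The 6 peaks inside Acsl4 in the libraries labelled control-GFP 1 and knockout-GFP 1 were found in 0 of the 2 libraries labelled knockout-Acsl4 and in 2 of the 4 labelled GFP, which restates the pattern and does not test overexpression as labelled. Open chromatin of the endogenous gene stays open. The library labelled knockout-GFP 2 held 88.6% of 1407 other regions shared by the libraries labelled control-GFP 1 and knockout-GFP 1, and 7 of 11 on chromosome X. A single locus would then be missed at 11.4% or 36.4%. Taken as 6 separate peaks, missing all would have a binomial probability of 2.16e-06 or 0.00231. That the 6 count as a single locus was decided after the values were seen, so this test does not decide. DNA of the Acsl4 cDNA could give peaks with sharp edges. The median edge distance of the 6 was 4.25 bp, against 68 bp for all other shared regions (permutation p = 1e-05, the smallest possible). Among regions of like score it was 15.5 bp for all 121 (permutation p = 0.0884) and 48.5 bp for the 23 at gene ends (permutation p = 1e-05). For the 98 outside gene ends, where the 6 lie, it was 7.25 bp (permutation p = 0.177). These values go different ways, which leaves this open. Too few reads in the library labelled knockout-Acsl4 1 stays open too. It held 65.2% of 89 knockout-GFP 1 regions of like score, over the limit set beforehand, and 51 of the 63 outside gene ends (81.0%). That limit took the 6 as missed separately, while a single locus would be missed at 34.8%. Of regions outside gene ends in 4 or fewer libraries, like the 6, it held 10 of 18. This last filter counts the library itself, which lowers its rate by construction, so it decides nothing. Whether a label is wrong was not tested, although the title of the library labelled knockout-Acsl4 2 carries a short code whose number differs from its replicate number, and no sample was regrouped.

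The low gene-end share of the library labelled knockout-Acsl4 2 is argued not to come from another genome build, because 68% of its 50 best peaks overlapped a peak of another list. An effect of Acsl4 stays open. The libraries labelled knockout-Acsl4 differed (lower bound 31.7% against upper bound 5.40%) but both lay below the 66.7% and 75.0% of knockout-GFP. The library labelled control-GFP 2, by its label without added Acsl4, was also low (21.6%). Relative to shifted peaks, the library labelled knockout-Acsl4 1 stood at 10.4 times, near the 11.1 and 11.4 of knockout-GFP. Calls close to the threshold on sparse reads remain a candidate explanation for the library labelled knockout-Acsl4 2. There 59.1% of peaks had a −log10 q under 2, against at most 33.2% in the other lists.

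The excess of knockout-only over control-only regions (234 against 25) went with the library labelled control-GFP 2, whose pair had fewer regions in 3 of 3 splits. The length of its list is argued against as the whole cause, because at equal lengths 58 regions were knockout-only against 17 control-only (77.3%, 95% exact interval 66.2 to 86.2). Other properties of that library stay open, as its pair was still lower in 3 of 3 splits at equal lengths. Loss of Rictor stays open, as the ratio of 9.36 lay between the 7.62 and 155 of the other splits, while at equal lengths its 3.41 lay below both (5.88 and 5). Whether these regions lie near the calling threshold is undecided, with a highest median score percentile of 49.9 and bootstrap intervals of the 2 medians from 43.2 to 54.8, which include the limit of 50 set beforehand.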
